A study of Mus musculus with 6 samples.

How the data were processed

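RNA from bone marrow-derived macrophages of wild-type and Endov knockout mice was extracted with RNeasy columns and made into libraries with the NEBNext Ultra RNA kit, per the labels' protocols, and sequenced on an Illumina NovaSeq, per the series description. There were 3 libraries per group, and the groups were taken from the genotype labels. The estimated count of each transcript in each library was deposited by the authors as kallisto output, per the file headers. kallisto 0.46.0, sleuth 0.30.0 and the build GRCm38.p6 are named per the submitters' processing notes; the index and options are not given in the sources used here. The deposited table of all libraries holds a normalized signal per transcript, which equals the estimated count times 1 factor per library (0.971 to 1.06). TPM was deposited by the authors beside each estimated count, per the file headers. The TPM used in alternatives was computed anew from the deposited estimated counts and effective transcript lengths.

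Each deposited file held 118783 transcripts, of which 116710 (98.3%) were matched by identifier, without its version, to GENCODE release M21, giving 35944 genes. The 2073 others held 0.519% to 0.531% of the counts and were left out of gene tests. Estimated counts were summed per gene and rounded. The totals were 21494411, 23113407 and 21558047 in wild-type replicates 13, 14 and 15 and 22006954, 21962467 and 20687373 in knockout replicates 16, 17 and 18. Pairs of libraries differed by a chi-square per degree of freedom of 2.88 to 6.03 within groups and 8.60 to 18.3 between groups. No pair agreed within counting noise, so no libraries were merged; this does not show that they came from separate cultures.

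The main test was the two-sided quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, after filterByExpr and TMM scaling (factors 0.989 to 1.01), with genotype as the only term and a Benjamini-Hochberg adjusted p under 0.05. Adjusted p-values of genes and transcripts in the text are from this test unless another is named. Standard errors were computed from the fold change and F. Transcripts were tested in the same way, without the uncertainty of read assignment. Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, correlation 0.01), adjusted over 28 lists; 20 passed, 14 up and 6 down, none with a correlation estimated per list (0), where the adjusted p of those lists ran from 0.0602 to 0.726, and 17 with fry, which asks only whether a list moves one way. Unadjusted p was under 0.05 for 2748 genes. Alternatives were DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1), log2(TPM + 0.1) and the deposited signal, other scalings and filters, a transcript-length offset, and leaving out each library. Near-identical transcripts were sought with BLAST 2.17.0 and shared 31-base words; permutation tests and tables used Python 3.11.15, SciPy 1.17.1 and pandas 2.3.3.

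The tests, the lists, the alternatives and the naming rule were fixed before the data were examined, except alternatives without immunoglobulin genes or without genes within 10 Mb of Endov, which were added after seeing the data. The rule named Endov, Ccl2, the 12 largest increases and decreases among genes past the threshold with separated groups and a mean of at least 1 CPM in a group, and in each list the 2 members of smallest p in each direction. It took 137 genes, of which 95 passed. Of the 42 that did not, most are given only as ranges: their knockout over wild-type folds ran from 0.593 to 1.38 and their adjusted p from 0.0504 to 0.974. Genes outside the rule are said to be chosen after their values were seen, save Pirb, named as a copy of Pira2.

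The gene test was tested on simulated data drawn from the wild-type means and the library sizes, with 50 genes changed at each fold. Genes with few counts were never among those changed. The gene test recovered 30, 45, 47 and 50 of them at folds of 1.25, 1.5, 2 and 4. It made 8 false calls among the 12085 unchanged genes that passed the filter, of 12298 simulated. The simulated genes were independent, with a dispersion set by the trend and no error of read assignment. On the real data the test may therefore do worse. Coordinates are those of GRCm38.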

Results

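Gene expression was measured by RNA sequencing in macrophages grown in culture from mouse bone marrow. The mice had a C57BL/6N background. Endov encodes endonuclease V, an enzyme that in mammals cuts RNA at inosine, the base that arises when adenosine is deaminated. The comparison asks which genes differ in macrophages of mice in which Endov was deleted. The wild-type group held 3 libraries (replicates 13, 14 and 15) and the knockout group held 3 (replicates 16, 17 and 18), from 3 mice per group according to the series description. Each library held between 20687373 and 23113407 estimated counts. The p-values measure only the spread between these libraries.

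Endov itself was lower in each knockout library than in each wild-type library. Its level was 10.7, 10.8 and 12.02 CPM (counts relative to the scaled library total) in wild-type replicates 13, 14 and 15. It was 4.98, 4.27 and 4.41 CPM in knockout replicates 16, 17 and 18. The mean went from 11.2 ± 0.724 to 4.55 ± 0.376 CPM (SD, n = 3 per group), a 2.45-fold decrease (log2 fold change -1.30, SE 0.11, edgeR quasi-likelihood adjusted p = 2.42e-06). Endov (ENSMUSG00000039850.16) lies on chromosome 11 at 119491347 to 119511437 on the plus strand of GRCm38. The protein-coding transcript ENSMUST00000106244.8, with 9 exons, held 156 ± 48.6 estimated counts in wild type and 35.02 ± 32.1 in knockout. Another protein-coding transcript, ENSMUST00000106245.8 with 8 exons, went the other way, from 15.2 ± 26.3 to 38.5 ± 25.5 estimated counts. The 4 Endov transcripts with enough counts did not pass the transcript test, with adjusted p from 0.629 to 0.955. Which part of the gene was deleted is not given in the sources used here, so the remaining counts cannot be placed inside or outside it. With limma on TPM and no filter on low values the adjusted p of Endov was 0.0830, and over all alternatives it ran from 5.00e-23 to 0.0830.

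**Figure D1:**
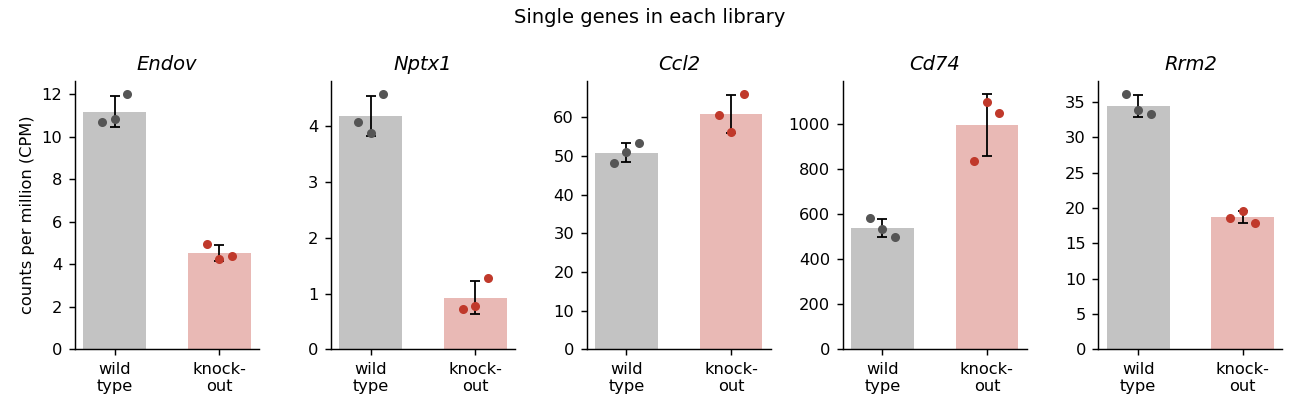
Level in CPM of Endov, Nptx1, Ccl2, Cd74 and Rrm2 in wild-type and knockout libraries. Points are single libraries, bars are means and error bars are SD (n = 3 per group); Endov had a mean of 11.2 CPM in wild type and 4.55 CPM in knockout.

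In knockout cultures 34 of 55 interferon-stimulated genes, 9 of 11 genes of MHC class II presentation and 12 of 24 neutrophil markers rose, and 43 of 50 cell cycle genes fell. These 4 lists passed as sets with camera but not with an estimated correlation, where the adjusted p was 0.0602, 0.0739, 0.0602 and 0.0602 in that order. Of 12498 genes tested, 1119 changed (8.95%, adjusted p under 0.05), 652 of them higher and 467 lower in knockout. The median fold was 1.27 among genes that rose and 1.34 among genes that fell. A change of 2-fold or more was found for 154 genes, 110 higher and 44 lower. The knockout values lay all above or all below the wild-type values for 1106 of the changed genes, and for 26.7% of tested genes, where chance gives 10%. Replicates varied by 4.93% beyond counting noise. Log2 CPM correlated across genes, which are not independent replicates, at 0.992 to 0.993 between libraries of a group and at 0.984 to 0.988 between groups. The first principal component held 46.5% of the variance. Upper-quartile scaling called 559 genes higher and 606 lower, so the balance of directions depended on the scaling. The count was 709 without knockout replicate 17, 522 with a transcript-length offset and 166 to 362 with limma on TPM, and 299 genes were lower without knockout replicate 18.

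Of 55 interferon-stimulated genes measured, 34 rose and 0 fell over all genes tested and 40 rose and 0 fell adjusted over the list alone, with a median log2 fold change of 0.35. Xaf1, which promotes apoptosis, rose 2.87-fold from 13.01 ± 0.462 to 37.4 ± 1.93 CPM (adjusted p = 1.81e-09), and Gbp3, a guanylate-binding GTPase of host defence, rose 2.68-fold from 24.1 ± 2.98 to 64.5 ± 3.29 CPM (adjusted p = 1.04e-08). Isg20 and Ifi27l2a had knockout over wild-type folds of 0.789 and 0.953 and did not pass (adjusted p = 0.472 and 0.683). Without wild-type replicate 13, Ifi27l2a passed as lower in knockout (log2 fold change -0.19, adjusted p = 0.0494). For the list, camera gave an adjusted p of 3.64e-21 (6.34e-24 to 0.0602 over the alternatives), and the adjusted p = 0.0602 with an estimated correlation. Of 11 genes of MHC class II presentation, 9 rose and 0 fell over all genes tested and 9 rose and 0 fell adjusted over the list alone, with a median log2 fold change of 0.84. Cd74, the invariant chain, rose 1.85-fold from 539 ± 41.3 to 995 ± 139 CPM (adjusted p = 5.13e-06), and H2-DMb1, part of the peptide-loading protein, rose 1.56-fold from 57.3 ± 2.78 to 89.3 ± 6.40 CPM (adjusted p = 4.12e-06). The fitted log2 fold change of Xaf1 was 0.61 with a transcript-length offset, against 1.52 without it. For MHC class II, camera gave an adjusted p of 3.04e-09 (2.60e-10 to 0.0739 over the alternatives), and the adjusted p = 0.0739 with an estimated correlation. In the same libraries the median log2 fold change of 11 marker lists was 0.77 for neutrophil markers, 0.63 for T and NK cell markers, 0.50 for B lineage markers, 0.50 for mast cell and basophil markers, 0.48 for monocyte markers, 0.27 for dendritic cell markers, 0.23 for stromal and endothelial markers, 0.12 for eosinophil markers, 0.05 for macrophage markers, -0.04 for osteoclast markers and -0.19 for erythroid and megakaryocyte markers.

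Of 50 cell cycle genes measured, 0 rose and 43 fell over all genes tested and 0 rose and 46 fell adjusted over the list alone, with a median 1.52-fold decrease. Rrm2, a subunit of ribonucleotide reductase, fell 1.84-fold from 34.4 ± 1.501 to 18.7 ± 0.844 CPM (adjusted p = 5.04e-07). Top2a, a DNA topoisomerase of dividing cells, fell 1.49-fold from 87.2 ± 5.14 to 58.5 ± 0.653 CPM (adjusted p = 3.31e-06). E2f1, a transcription factor of S-phase entry, did not pass, at 50.8 ± 0.785 to 52.9 ± 2.96 CPM (adjusted p = 0.582). For the list, camera gave an adjusted p of 4.81e-32 (1.39e-38 to 0.0602 over the alternatives), and the adjusted p = 0.0602 with an estimated correlation. In the same libraries 2 of 10 erythroid and megakaryocyte markers fell, with a list median of -0.19 on the log2 scale. The medians of all 11 marker lists ran from -0.19 for erythroid to 0.77 for neutrophil markers. The erythroid list passed with camera (adjusted p = 0.0146) but not with an estimated correlation (adjusted p = 0.206), and its call was lost without wild-type replicate 14 (adjusted p = 0.149) or knockout replicate 17 (0.0870). Top2a reached an adjusted p of 0.0630 under another test, scaling or filter.

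Of 32 chemokines and chemokine receptors, 12 rose and 3 fell over all genes tested and 16 rose and 5 fell adjusted over the list alone. Cxcl9, a ligand of CXCR3, rose 2.65-fold from 10.8 ± 3.13 to 28.7 ± 5.99 CPM (adjusted p = 5.34e-05), and Ccl6 rose 1.44-fold (adjusted p = 2.80e-05). Cx3cr1, the fractalkine receptor, fell 2.41-fold from 42.8 ± 5.63 to 17.8 ± 1.92 CPM (adjusted p = 6.57e-07), and Cxcl14 fell 1.36-fold (adjusted p = 7.79e-05). Ccl2, the monocyte chemoattractant, rose 1.20-fold from 50.9 ± 2.54 to 60.9 ± 4.93 CPM (adjusted p = 0.0152). The call of Ccl2 was lost without wild-type replicate 13 (adjusted p = 0.0746), knockout replicate 16 (0.0528) or knockout replicate 18 (0.0792), and its adjusted p ran from 0.000212 to 0.238 over all alternatives. For the chemokine list, camera gave an adjusted p of 8.99e-05 (2.22e-05 to 0.0695 over the alternatives), and the adjusted p = 0.0695 with an estimated correlation. Beside these genes, the median log2 fold changes of the 11 marker lists ran from -0.19 for erythroid to 0.77 for neutrophil markers, with 0.63 for T and NK cell, 0.50 for B lineage and 0.48 for monocyte markers. Cxcl9 reached an adjusted p of 0.0882 under another test, scaling or filter.

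Of 36 genes of inflammatory activation, 14 rose and 0 fell over all genes tested and 17 rose and 1 fell adjusted over the list alone. Acod1, which makes itaconate, rose 2.35-fold from 6.58 ± 2.21 to 15.4 ± 1.41 CPM (adjusted p = 0.000165), and Icam1, an adhesion molecule, rose 1.247-fold (adjusted p = 0.000194). Of 28 genes of alternative activation, 8 rose and 1 fell over all genes tested and 11 rose and 3 fell adjusted over the list alone. Chil3, a chitinase-like protein, rose 1.75-fold (adjusted p = 6.80e-07), and Timd4, a phosphatidylserine receptor, rose 10.6-fold from 0.198 ± 0.0574 to 2.14 ± 0.259 CPM (adjusted p = 1.60e-05). Arg1, arginase 1, fell 2.09-fold from 8.44 ± 0.766 to 4.01 ± 1.86 CPM (adjusted p = 0.00859). For inflammatory activation camera gave an adjusted p of 9.49e-06 (3.34e-06 to 0.0602 over the alternatives), and the adjusted p = 0.0602 with an estimated correlation. For alternative activation camera gave an adjusted p of 0.000838 (0.000330 to 0.0602 over the alternatives), and the adjusted p = 0.0602 with an estimated correlation. In the same libraries the median log2 fold changes of the 11 marker lists ran from -0.19 for erythroid to 0.77 for neutrophil markers. Acod1 and Arg1 reached an adjusted p of 0.104 and 0.290 under another test, scaling or filter.

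Some markers of granulocytes rose in knockout cultures. Of 24 markers of neutrophils and their precursors, 12 rose and 2 fell over all genes tested and 15 rose and 2 fell adjusted over the list alone. Ltf, lactoferrin, rose 2.01-fold from 74.6 ± 2.74 to 150.1 ± 3.48 CPM (adjusted p = 1.81e-09), and Ngp, a granule protein, rose 2.05-fold from 105 ± 5.80 to 216 ± 7.54 CPM (adjusted p = 2.93e-09). Mmp9, a gelatinase that macrophages also make, fell 1.67-fold (adjusted p = 3.31e-06). For the list, camera gave an adjusted p of 4.69e-10 (1.23e-11 to 0.0602 over the alternatives), and the adjusted p = 0.0602 with an estimated correlation. Of 10 markers of mast cells and basophils, 5 rose and 0 fell over all genes tested and 6 rose and 0 fell adjusted over the list alone. Prss34 and Cpa3, both proteases, rose 4.62-fold and 3.33-fold (adjusted p = 0.000680 and 0.00193), but at low levels. Prss34 went from 0.349 ± 0.0238 to 1.63 ± 0.414 CPM and Cpa3 from 0.683 ± 0.324 to 2.29 ± 0.180 CPM. For that list camera gave an adjusted p of 6.16e-05 (7.28e-08 to 0.0739 over the alternatives), and the adjusted p = 0.0739 with an estimated correlation. Of 4 eosinophil markers, too few for a set test, 1 rose and 0 fell over all genes tested and 2 rose and 1 fell adjusted over the list alone; Prg2, a granule protein, rose 2.45-fold (adjusted p = 4.04e-05). Cpa3 reached an adjusted p of 0.322 under another test, scaling or filter.

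Some markers of stromal and lymphoid cells rose. Of 29 stromal and endothelial markers, 8 rose and 0 fell over all genes tested and 9 rose and 0 fell adjusted over the list alone. Col1a1 and Col1a2, the chains of type I collagen, rose 1.89-fold and 1.80-fold (adjusted p = 3.20e-07 and 2.02e-07). For this list camera gave an adjusted p of 3.86e-06 (7.44e-07 to 0.0686 over the alternatives), and the adjusted p = 0.0686 with an estimated correlation. Of 12 B lineage markers, 3 rose and 0 fell over all genes tested and 3 rose and 0 fell adjusted over the list alone. Ighm and Igkc, immunoglobulin constant regions, rose 1.80-fold and 1.43-fold (adjusted p = 1.56e-06 and 0.000128). For B lineage markers camera gave an adjusted p of 1.49e-05 (3.34e-06 to 0.0602 over the alternatives), and the adjusted p = 0.0602 with an estimated correlation. Of 18 T and NK cell markers, 3 rose and 0 fell over all genes tested and 3 rose and 0 fell adjusted over the list alone. Among them rose Gzmb, granzyme B, 2.54-fold (adjusted p = 0.0185; lost without wild-type replicate 13 (adjusted p = 0.0786), wild-type replicate 14 (0.0558), knockout replicate 17 (0.119) or knockout replicate 18 (0.0521); 0.000280 to 0.203 over all alternatives), and Thy1 1.60-fold (adjusted p = 0.0380; lost without wild-type replicate 13 (adjusted p = 0.0896), wild-type replicate 14 (0.0717), wild-type replicate 15 (0.0873), knockout replicate 16 (0.142) or knockout replicate 17 (0.122); 0.0177 to 0.718 over all alternatives). For T and NK cell markers camera gave an adjusted p of 3.44e-05 (7.39e-06 to 0.0602 over the alternatives), and the adjusted p = 0.0602 with an estimated correlation. Igkc reached an adjusted p of 0.0525 under another test, scaling or filter. Levels of Gzmb and Thy1 were low, from 0.760 ± 0.312 to 1.93 ± 0.532 CPM and from 1.99 ± 0.0871 to 3.17 ± 0.394 CPM.

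Of 14 monocyte markers, 5 rose and 1 fell over all genes tested and 6 rose and 2 fell adjusted over the list alone. Cd177, a surface protein known from neutrophils, rose 2.13-fold (adjusted p = 3.81e-05); for the list camera gave an adjusted p of 0.000287 (8.15e-05 to 0.0602 over the alternatives), and the adjusted p = 0.0602 with an estimated correlation. Of 18 dendritic cell markers, 3 rose and 0 fell over all genes tested and 6 rose and 0 fell adjusted over the list alone. Cd24a rose 1.83-fold and Irf8, a transcription factor, 1.21-fold (adjusted p = 0.000491 and 0.00252). For dendritic cells camera gave an adjusted p of 0.000172 (6.79e-05 to 0.0602 over the alternatives), and the adjusted p = 0.0602 with an estimated correlation. Of 25 macrophage markers, 2 rose and 0 fell over all genes tested and 4 rose and 2 fell adjusted over the list alone, with a median log2 fold change of 0.05. Fcgr1, an Fc receptor, rose 1.51-fold (adjusted p = 1.86e-06). For macrophage markers camera gave an adjusted p of 0.0393 (0.0235 to 0.323 over the alternatives), and the adjusted p = 0.323 with an estimated correlation; the call was lost without wild-type replicate 15 (adjusted p = 0.186), knockout replicate 17 (0.0517) or knockout replicate 18 (0.0960). Cd177, Cd24a and Irf8 reached an adjusted p of 0.0969, 0.0619 and 0.0882 under another test, scaling or filter.

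Of 10 erythroid and megakaryocyte markers, 0 rose and 2 fell over all genes tested and 0 rose and 3 fell adjusted over the list alone. Tfrc, the transferrin receptor, fell 1.43-fold (adjusted p = 1.96e-05) and Car2, a carbonic anhydrase, fell 1.75-fold (adjusted p = 0.00988). For the list camera gave an adjusted p of 0.0146 (0.00512 to 0.206 over the alternatives), and the adjusted p = 0.206 with an estimated correlation; the call was lost without wild-type replicate 14 (adjusted p = 0.149) or knockout replicate 17 (0.0870). Of 13 osteoclast markers, 2 rose and 3 fell over all genes tested and 6 rose and 5 fell adjusted over the list alone. Clcn7, a lysosomal chloride transporter, rose 1.24-fold (adjusted p = 0.000433), and the list did not pass (camera adjusted p = 0.933). Car2 and Clcn7 reached an adjusted p of 0.136 and 0.202 under another test, scaling or filter.

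**Figure D2:**
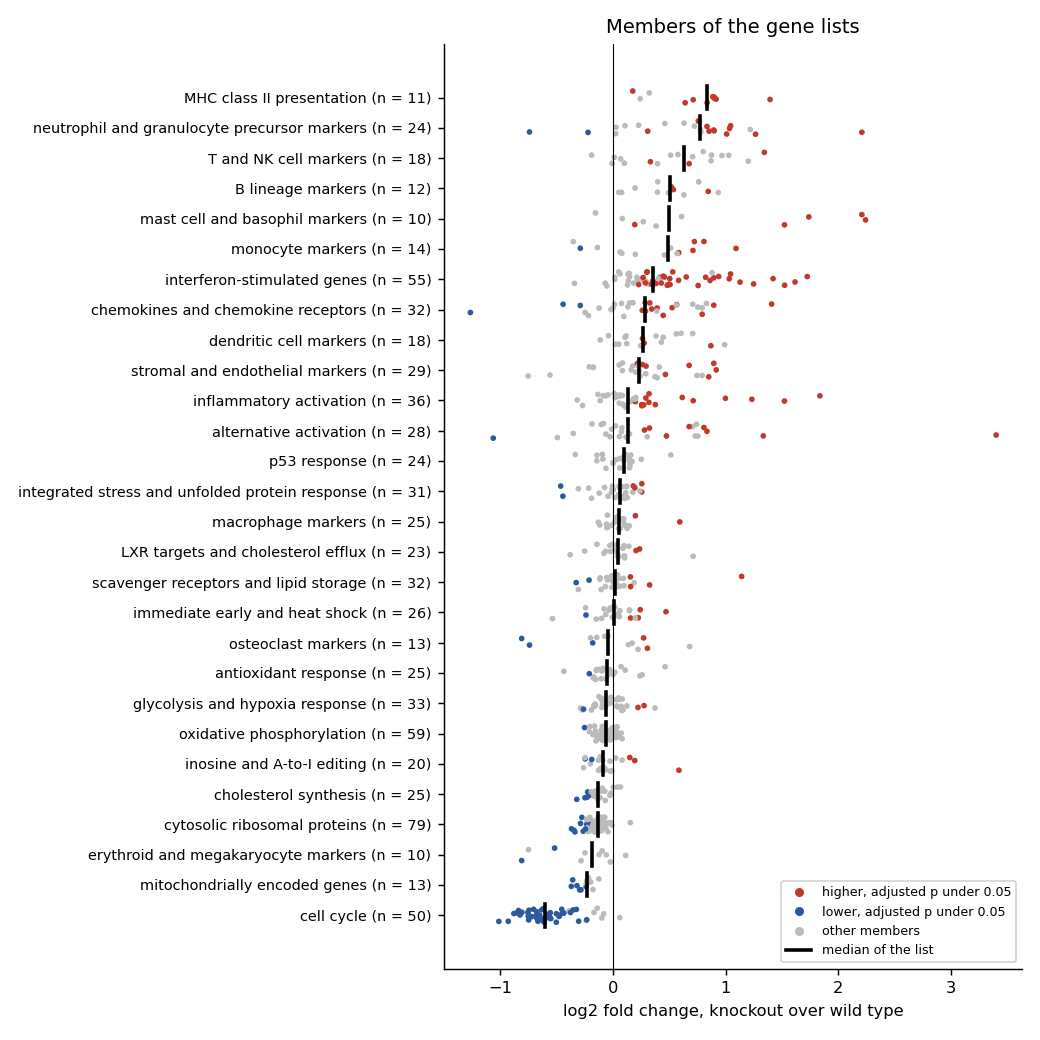
Log2 fold change of knockout over wild type for each member of the 28 gene lists tested as sets, ordered by median. Each point is a gene, coloured where it passed an adjusted p under 0.05 over all genes, and black bars are medians; MHC class II had a median of 0.84 and the cell cycle a median of -0.60.

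Of 25 genes of cholesterol synthesis, 0 rose and 6 fell over all genes tested and 0 rose and 12 fell adjusted over the list alone, with a median 1.10-fold decrease. Hsd17b7, an enzyme of the pathway, fell 1.2503-fold (adjusted p = 0.00861). For the list camera gave an adjusted p of 3.40e-05 (9.46e-07 to 0.277 over the alternatives), and the adjusted p = 0.277 with an estimated correlation. Of 23 LXR targets and efflux genes, 2 rose and 0 fell over all genes tested and 2 rose and 0 fell adjusted over the list alone; Pltp, the phospholipid transfer protein, rose 1.18-fold (adjusted p = 0.00216). Of 32 genes of scavenger receptors and lipid storage, 4 rose and 2 fell over all genes tested and 4 rose and 3 fell adjusted over the list alone; Ctsl, a lysosomal protease, fell 1.255-fold (adjusted p = 0.000257). Neither of these last lists passed as a set (camera adjusted p = 0.280 and 0.455). Hsd17b7, Pltp and Ctsl reached an adjusted p of 0.284, 0.0642 and 0.104 under another test, scaling or filter.

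Of 79 cytosolic ribosomal protein genes, 0 rose and 9 fell over all genes tested and 0 rose and 28 fell adjusted over the list alone. Among those that fell were Rpl3 1.14-fold (adjusted p = 0.0148; lost without knockout replicate 17 (adjusted p = 0.0763) or knockout replicate 18 (0.0501); 0.000637 to 0.0962 over all alternatives) and Rps26 1.19-fold (adjusted p = 0.0161; lost without knockout replicate 16 (adjusted p = 0.0607) or knockout replicate 18 (0.0646); 1.64e-05 to 0.175 over all alternatives). For the list camera gave an adjusted p of 8.53e-10 (3.78e-17 to 0.492 over the alternatives), and the adjusted p = 0.492 with an estimated correlation. The share of a library's counts in all genes with symbols that begin as those of ribosomal proteins, a wider set than the list, was 3.25, 3.52 and 3.07% in wild-type replicates 13, 14 and 15 and 3.04, 3.06 and 2.85% in knockout replicates 16, 17 and 18. Of 13 mitochondrially encoded genes, 0 rose and 7 fell over all genes tested and 0 rose and 12 fell adjusted over the list alone; mt-Nd3 fell 1.29-fold and mt-Co3 1.18-fold (adjusted p = 0.00714 and 0.00802). For these genes camera gave an adjusted p of 3.44e-05 (3.65e-07 to 0.290 over the alternatives), and the adjusted p = 0.290 with an estimated correlation. The share of all genes with mt- symbols overlapped between the groups, at 1.59, 1.31 and 1.501% in wild-type replicates 13, 14 and 15 and 1.36, 1.29 and 1.14% in knockout replicates 16, 17 and 18. Of 59 nuclear genes of oxidative phosphorylation, 0 rose and 1 fell over all genes tested and 0 rose and 0 fell adjusted over the list alone. The member that fell was Cox7c 1.19-fold (adjusted p = 0.0282; lost without wild-type replicate 14 (adjusted p = 0.0915), knockout replicate 17 (0.0795) or knockout replicate 18 (0.125); 1.70e-05 to 0.196 over all alternatives). For oxidative phosphorylation camera gave an adjusted p of 0.0127 (1.53e-05 to 0.896 over the alternatives), and the adjusted p = 0.726 with an estimated correlation; the call was lost without wild-type replicate 14 (adjusted p = 0.896) or knockout replicate 18 (0.175). mt-Nd3 and mt-Co3 reached an adjusted p of 0.182 and 0.231 under another test, scaling or filter.

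The list of genes linked to inosine and A-to-I editing, not all of which act on inosine, did not pass as a set (camera adjusted p = 0.304). Of 20 measured, 3 rose and 2 fell over all genes tested and 3 rose and 2 fell adjusted over the list alone. Samhd1, a dNTP hydrolase, rose 1.4996-fold from 304 ± 11.5 to 456 ± 22.3 CPM (adjusted p = 1.56e-06), and Azin1, whose mRNA is a known target of A-to-I editing, fell 1.19-fold (adjusted p = 0.00278). Of 24 genes of the p53 response, 0 rose and 0 fell over all genes tested and 0 rose and 0 fell adjusted over the list alone by edgeR; 6 had an unadjusted p under 0.05, and over all genes DESeq2 called 1 and limma-voom 0. For the p53 list camera gave an adjusted p of 0.0430 (0.0194 to 0.192 over the alternatives), and the adjusted p = 0.192 with an estimated correlation; the call was lost without wild-type replicate 13 (adjusted p = 0.0631), wild-type replicate 15 (0.130), knockout replicate 17 (0.139) or knockout replicate 18 (0.0578). Azin1 reached an adjusted p of 0.564 under another test, scaling or filter.

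Of 31 genes of the integrated stress and unfolded protein response, 4 rose and 2 fell over all genes tested and 4 rose and 3 fell adjusted over the list alone. Hspa5, the chaperone BiP, rose 1.19-fold (adjusted p = 0.00730), while Asns, asparagine synthetase, and Mthfd2, a mitochondrial folate enzyme, fell 1.38-fold and 1.36-fold (adjusted p = 0.00565 and 0.00323). Of 33 genes of glycolysis and the hypoxia response, 2 rose and 1 fell over all genes tested and 2 rose and 1 fell adjusted over the list alone; Pfkfb3, a regulator of glycolysis, rose 1.17-fold (adjusted p = 0.00528). Of 26 immediate early and heat shock genes, 4 rose and 1 fell over all genes tested and 5 rose and 1 fell adjusted over the list alone; Ier3 rose 1.39-fold and Jund 1.17-fold (adjusted p = 0.00786 and 0.00773). Of 25 antioxidant genes, 0 rose and 1 fell over all genes tested and 0 rose and 0 fell adjusted over the list alone. As sets these lists did not pass, with camera adjusted p of 0.256, 0.432, 0.385 and 0.0564 in the order given. Hspa5, Asns, Mthfd2, Pfkfb3, Ier3 and Jund reached an adjusted p of 0.332, 0.245, 0.146, 0.151, 0.0702 and 0.0642 under another test, scaling or filter.

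Some list members passed with all libraries but not with each library left out. Among these members, Dgat2 had a low level, from 0.950 ± 0.298 CPM in wild type to 2.12 ± 0.425 CPM in knockout. Those that rose were Pnp 1.14-fold (adjusted p = 0.0387; lost without wild-type replicate 13 (adjusted p = 0.0773), wild-type replicate 14 (0.0557), wild-type replicate 15 (0.103), knockout replicate 17 (0.201) or knockout replicate 18 (0.113); 0.00304 to 0.264 over all alternatives), Abcg1 1.15-fold (adjusted p = 0.0179; lost without wild-type replicate 13 (adjusted p = 0.0663) or knockout replicate 18 (0.0786); 0.000823 to 0.249 over all alternatives), Dgat2 2.21-fold (adjusted p = 0.0195; lost without wild-type replicate 13 (adjusted p = 0.0675), wild-type replicate 15 (0.0682), knockout replicate 17 (0.0523) or knockout replicate 18 (0.102); 0.000945 to 0.158 over all alternatives) and Dgat1 1.252-fold (adjusted p = 0.0305; lost without wild-type replicate 13 (adjusted p = 0.111), wild-type replicate 14 (0.0538), knockout replicate 16 (0.0995) or knockout replicate 17 (0.122); 0.0158 to 0.449 over all alternatives). Higher too were Cd14 1.15-fold (adjusted p = 0.0243; lost without wild-type replicate 13 (adjusted p = 0.110), wild-type replicate 15 (0.0530), knockout replicate 17 (0.122) or knockout replicate 18 (0.0629); 0.00148 to 0.122 over all alternatives), Ctsk 1.21-fold (adjusted p = 0.00784; lost without knockout replicate 16 (adjusted p = 0.0549); 0.000530 to 0.0920 over all alternatives), Vegfa 1.21-fold (adjusted p = 0.0117; lost without wild-type replicate 13 (adjusted p = 0.0572) or knockout replicate 17 (0.0736); 4.93e-06 to 0.275 over all alternatives) and Pdia4 1.19-fold (adjusted p = 0.0329; lost without wild-type replicate 13 (adjusted p = 0.111), wild-type replicate 15 (0.0637), knockout replicate 17 (0.0605) or knockout replicate 18 (0.117); 1.84e-05 to 0.442 over all alternatives). Those that fell were Impdh2 1.14-fold (adjusted p = 0.0264; lost without wild-type replicate 13 (adjusted p = 0.0525), wild-type replicate 15 (0.0850), knockout replicate 16 (0.0517), knockout replicate 17 (0.120) or knockout replicate 18 (0.0792); 0.0154 to 0.270 over all alternatives), Spp1 1.16-fold (adjusted p = 0.0411; lost without wild-type replicate 14 (adjusted p = 0.103), wild-type replicate 15 (0.111), knockout replicate 16 (0.0679), knockout replicate 17 (0.125) or knockout replicate 18 (0.147); 8.09e-05 to 0.444 over all alternatives), Sc5d 1.17-fold (adjusted p = 0.00939; lost without knockout replicate 17 (adjusted p = 0.0673); 0.00132 to 0.158 over all alternatives) and Anxa1 1.17-fold (adjusted p = 0.0108; lost without knockout replicate 17 (adjusted p = 0.0727); 5.00e-05 to 0.205 over all alternatives). Lower too were Ccr2 1.22-fold (adjusted p = 0.0194; lost without wild-type replicate 13 (adjusted p = 0.0807), knockout replicate 16 (0.0916) or knockout replicate 17 (0.0957); 0.00249 to 0.251 over all alternatives), Pgk1 1.20-fold (adjusted p = 0.0272; lost without wild-type replicate 14 (adjusted p = 0.0683), knockout replicate 16 (0.0513) or knockout replicate 18 (0.0723); 2.01e-06 to 0.318 over all alternatives), Srxn1 1.16-fold (adjusted p = 0.0312; lost without wild-type replicate 14 (adjusted p = 0.102), knockout replicate 16 (0.126) or knockout replicate 17 (0.159); 0.000637 to 0.214 over all alternatives) and Fos 1.18-fold (adjusted p = 0.00962; lost without knockout replicate 16 (adjusted p = 0.0648); 0.000280 to 0.409 over all alternatives).

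Of 115 immunoglobulin genes tested, 63 changed, 44 up and 19 down, and they made up 55 of the 154 genes that changed by 2-fold or more. Ighv2-9-1 (chromosome 12, 113769850 to 113770302) rose 35.2-fold from 0.363 ± 0.241 to 13.01 ± 1.39 CPM (adjusted p = 2.57e-09). Igkv9-120 (chromosome 6, 68049983 to 68050456) fell 15.8-fold from 26.9 ± 2.84 to 1.69 ± 0.419 CPM (adjusted p = 1.77e-10), and Ighv6-6 fell 17.999-fold from 17.8 ± 0.803 to 0.975 ± 0.370 CPM (adjusted p = 4.10e-10). Ighv1-42 had 0 counts in wild type and 133 in knockout, at least 45.4-fold higher against a floor of 3 counts over the group. Igkv1-122 had 69 counts in wild type and 0 in knockout, at least 22.5-fold lower by the same floor. Igkv4-79 had 1 count in wild type and 200 in knockout, a ratio of 205 (exact 95% interval 36.3 to 8124); without wild-type replicate 14, which held that count, the fitted log2 fold change was 9.07 in place of 7.22. Intervals and floors cover counting error only. Other V segments that rose were Igkv14-100, Igkv3-1, Ighv1-12, Ighv4-1, Igkv6-32 and Ighv2-5, with log2 fold changes from 3.31 to 5.73. Without wild-type replicate 13 the fitted value went from 5.73 to 9.26 for Igkv14-100, which had 0 counts in the other wild-type libraries, and from 4.19 to 4.99 for Ighv1-12. Without wild-type replicate 14 that of Igkv3-1 went from 5.55 to 6.65. Other immunoglobulin genes that fell were Ighv5-4, Ighv10-1, Ighv10-3, Ighd, Ighv9-2, Igkv6-25 and Igkv4-55, with log2 fold changes from -3.15 to -1.73; that of Ighv9-2 was -2.70, and -3.38 without knockout replicate 16. V segments of a family resemble one another, so the count of a single segment is uncertain. Ighv1-12, Ighv9-2, Igkv6-25 and Igkv4-55 reached an adjusted p of 0.0550, 0.0776, 0.0659 and 0.0666 under another test, scaling or filter.

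**Figure D3:**
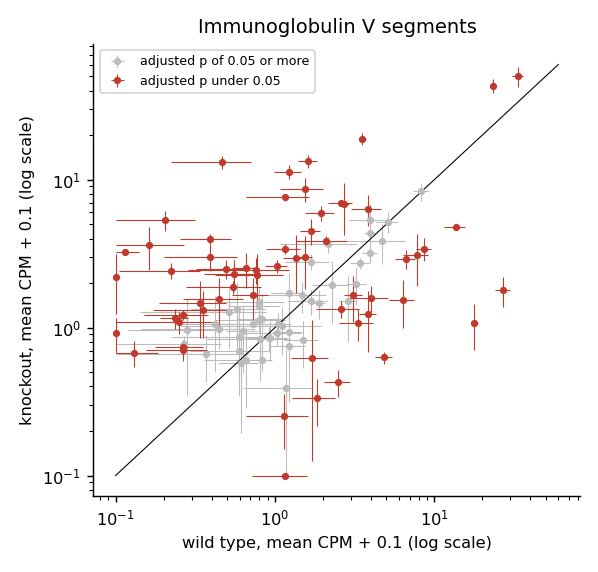
Mean CPM plus 0.1 of each tested immunoglobulin V segment in wild type (x axis) and knockout (y axis), both on log scales, with SD as error bars (n = 3 per group) and a line of equality. Segments lie on both sides of the line, with Igkv9-120 at 26.9 CPM in wild type and 1.69 CPM in knockout.

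Outside the immunoglobulin genes, several large changes were in genes with close relatives. Gm10184 (chromosome 17, 89908462 to 89910449) had 0 counts in wild type and 1621 in knockout, at least 553-fold higher against a floor of 3 counts over the group. Its transcript aligned to Kpna2 at 99.9% identity over 1968 of 1988 bases, and 95.8% of its 31-base words also occurred in Kpna2. Kpna2, a nuclear import receptor on chromosome 11 chosen after its values were seen, fell 2.58-fold from 67.4 ± 1.95 to 26.1 ± 0.548 CPM (adjusted p = 3.84e-10). Both genes summed held 67.5 ± 1.24 CPM in wild type and 51.2 ± 1.20 CPM in knockout, so the split of counts between them is uncertain. Pira2, a paired immunoglobulin-like receptor on chromosome 7, fell 5.99-fold from 78.2 ± 3.12 to 13.03 ± 1.01 CPM (adjusted p = 3.51e-12), and 30.4% of its 31-base words occurred in Pirb. Pira2 and Pirb summed held 542 ± 5.26 CPM in wild type and 524 ± 16.8 CPM in knockout, a 1.04-fold difference. The best alignment to Pirb covered only 55.7% of the Pira2 transcript, and no other relative was compared. The sum so cannot tell whether reads were divided differently, and the decrease of Pira2 is uncertain too. Gm20431 rose 10.1-fold from 0.402 ± 0.696 to 4.02 ± 3.75 CPM (adjusted p = 0.0166), a call lost without knockout replicate 17 (adjusted p = 0.153), and its adjusted p ran from 6.56e-32 to 0.586 over all alternatives. Its fitted log2 fold change of 3.33 became 9.46 without wild-type replicate 13, the only wild-type library with counts, 2.73 without wild-type replicate 14 and 2.22 without knockout replicate 17.

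Nptx1, a neuronal pentraxin beside Endov on chromosome 11 (119538719 to 119547753), fell 4.51-fold from 4.18 ± 0.361 to 0.928 ± 0.2998 CPM (adjusted p = 1.95e-05). Of 45 genes near Endov, 4 rose and 3 fell over all genes tested and 5 rose and 3 fell adjusted over the list alone; Cyth1 rose 1.21-fold (adjusted p = 0.00570). Also near Endov, Pgs1 1.14-fold (adjusted p = 0.0147; lost without knockout replicate 17 (adjusted p = 0.0610) or knockout replicate 18 (0.0653); 0.00837 to 0.167 over all alternatives) was higher and Slc25a10 1.15-fold (adjusted p = 0.0251; lost without wild-type replicate 13 (adjusted p = 0.0552), wild-type replicate 15 (0.0780), knockout replicate 17 (0.126) or knockout replicate 18 (0.0845); 0.0117 to 0.254 over all alternatives) lower. Counting all tested genes within 10 Mb of Endov, without Endov itself, 32 of 169 passed (18.9%). Among 12186 other genes of the autosomes and X, without immunoglobulin genes, 8.31% passed. Of 7 genes known to differ between C57BL/6J and C57BL/6N, 0 rose and 0 fell over all genes tested and 0 rose and 0 fell adjusted over the list alone by edgeR; 2 had an unadjusted p under 0.05, and over all genes DESeq2 called 0 and limma-voom 0. Ddx3y, a gene of the Y chromosome chosen after its values were seen, was read in each library at 1137 to 1319 counts. Of 4 sex-linked genes, 0 rose and 1 fell over all genes tested and 0 rose and 2 fell adjusted over the list alone. The lower gene was Eif2s3y 1.18-fold (adjusted p = 0.0147; lost without wild-type replicate 13 (adjusted p = 0.0636), knockout replicate 17 (0.0638) or knockout replicate 18 (0.0683); 0.00232 to 0.245 over all alternatives). Cyth1 reached an adjusted p of 0.449 under another test, scaling or filter.

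**Figure D4:**
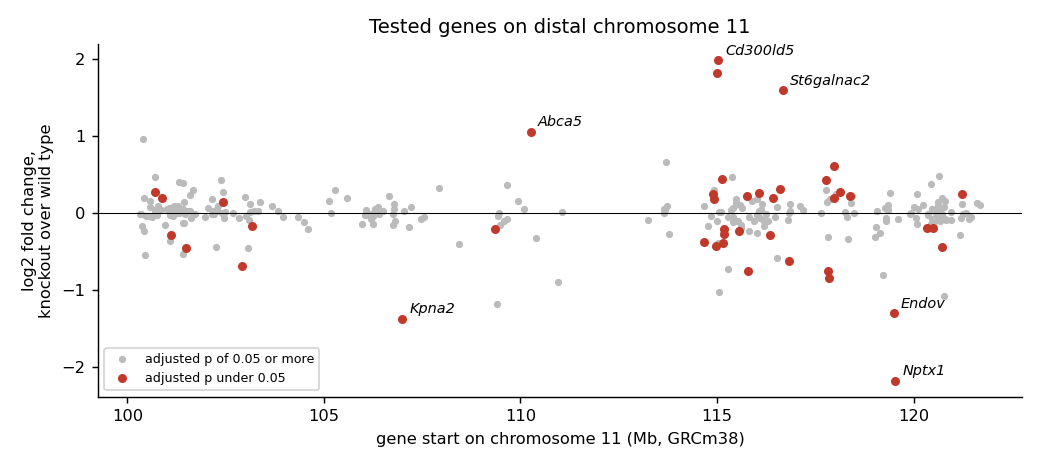
Log2 fold change of knockout over wild type for tested genes beyond 100 Mb of chromosome 11, by gene start in Mb (GRCm38). Each point is a gene, red where it passed an adjusted p under 0.05; Endov lies at -1.30 and Nptx1 at -2.17, and the other genes named were chosen after their values were seen.

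At the level of single transcripts, 95 of 31485 changed, 66 higher and 29 lower. They belonged to 94 genes, of which 83 also changed as genes. Transcript counts varied by 35.5% between replicates beyond counting noise. DESeq2 called 1101 transcripts. Without wild-type replicates 13, 14 and 15 in turn the count was 30, 14 and 22, and without knockout replicates 16, 17 and 18 it was 28, 16 and 16.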

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

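The alternatives without immunoglobulin genes and without genes within 10 Mb of Endov were chosen after seeing the data. Endov, the 103 other single genes called and the 20 lists called kept their direction under the alternatives run; the directions of genes not named and of transcripts were not compared. Of 2101 alternative values of 108 single genes, 1838 kept their side of the threshold, 262 lost it and 1 gained it, and of 448 values of 28 lists 403 kept it, 40 lost it and 5 gained it, all of the last for the antioxidant list. Of the single genes called, 76 kept their call with any library left out. Genes changed numbered 522 (328 higher, 194 lower) with a transcript-length offset, 362 (255, 107) with limma on log2(TPM + 1), 352 (244, 108) with log2(TPM + 0.1) and 166 (125, 41) without a TPM filter; the cause was not tested. At an adjusted p under 0.01 they numbered 587 (368, 219), those with a fold of at least 1.5 numbered 360 (205, 155), and 719 were lower at an adjusted p under 0.1. With 1 library left out, and so fewer samples, the count ran from 709 without knockout replicate 17 to 1024 without wild-type replicate 15 (427 to 589 higher, 282 to 435 lower). DESeq2 shared 849 of its 897 genes with the main test, voom 1073 of 1101 and upper-quartile scaling 1026 of 1165. Endov had a log2 fold change of -1.07 with limma on log2(TPM + 1) without a filter (adjusted p = 0.0830, 5.00e-23 to 0.0830 over all alternatives). With an estimated correlation 0 gene lists passed (unadjusted p under 0.05 for 13) and with fry 17 passed. DESeq2 called 1101 transcripts, and leaving out 1 library left 14 to 30. The gap between correlations within and between groups was 0.00404 over all tested genes and 0.117 over the 500 most variable genes. No paired analysis was possible because the groups share no replicate numbers. Without immunoglobulin genes 1034 genes passed and without genes within 10 Mb of Endov 1077. Depth limits V segments with few counts, such as Igkv4-79 with 1 count in wild type, whose ratio had an exact 95% interval of 36.3 to 8124.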

Other observations

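All tests of explanations in this part were chosen only after the result was seen, as were Ifng, the genes of the next paragraph and the splits of the libraries. The tests of a lower share of macrophages and of interferon-gamma replaced first versions that had been seen, whose values are given beside them.

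Jchain, the joining chain of secreted IgM and IgA, rose 1.45-fold from 31.7 ± 4.51 to 46.1 ± 2.20 CPM (adjusted p = 0.000545), beside the increase of Ighm, while Igha was at 142 ± 7.45 to 135 ± 7.69 CPM (adjusted p = 0.455) and Ighg2b at 81.7 ± 11.9 to 85.5 ± 8.46 CPM (adjusted p = 0.743) from wild type to knockout, and neither passed. In the CD300 family of myeloid receptors on chromosome 11, Cd300ld5 rose 3.95-fold from 15.1 ± 2.24 to 59.997 ± 6.17 CPM (adjusted p = 2.90e-09) and Cd300ld2 rose 3.51-fold (adjusted p = 0.00139), while Cd300ld fell 1.34-fold from 339 ± 11.1 to 253 ± 16.03 CPM (adjusted p = 5.86e-05). Of the 31-base words of Cd300ld5, 4.51% occurred in Cd300ld, and both genes summed held 355 ± 7.95 CPM in wild type and 312 ± 20.9 CPM in knockout. St6galnac2, a sialyltransferase, rose 3.02-fold and Abca5, a lipid transporter, 2.07-fold (adjusted p = 7.56e-05 and 0.000658). Gm1821 rose 2.28-fold (adjusted p = 3.10e-08), but 86.3% of its 31-base words occurred in Ubb. Both summed held 1219 ± 28.3 CPM in wild type and 1257 ± 48.5 CPM in knockout. The Gm1821 transcript ENSMUST00000227415.1 went from 0.227 ± 0.0866 to 33.7 ± 3.50 CPM, a smaller change than the knockout SD of the sum. The sum so cannot tell a gain from reads divided differently, and the increase of Gm1821 is uncertain. Jchain, Cd300ld2, St6galnac2 and Abca5 reached an adjusted p of 0.0719, 0.0516, 0.0511 and 0.249 under another test, scaling or filter.

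V segments of immunoglobulin genes differed between the groups at both large loci, with 29 of 51 changed at Igh and 31 of 51 at Igk. Reads divided differently between near-identical segments would leave the sum of each V family alike. Yet 14 of 30 families differed by 2-fold or more in their summed count, which argues against that as the whole cause. Of these, Ighv4, Igkv15 and Igkv19 hold a single segment each, whose sum could not show such a division. Igkv12 differed by only 2.005-fold. If the libraries of a group came from one pool of antibody-producing cells, segments would vary within a group little more than other genes. Their mean squared coefficient of variation beyond counting noise was 2.12 times that of other genes of like count. This ratio lay between the bounds of 2 and 5, which were set after the result was seen. The groups fell on different sides of the lower bound, at 1.77 times in wild type and 2.60 times in knockout. A shared pool within each group so stays open, although the series description gives 3 mice per group. Germline differences at these loci and an effect of genotype on the repertoire stay open too. Were a pool shared, the p-values of all gene, transcript and list tests would not measure the spread between mice.

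On chromosome 11 around Endov more genes changed than elsewhere, 18.9% within 10 Mb against a 95th percentile of 13.6% over 220 windows of as many genes, of which 3 were as high. An effect on the nearest neighbours alone is argued against by the 21.6% changed between 1 and 10 Mb from Endov. A stretch of DNA of another strain carried along with the deletion was proposed after this excess was seen, so the excess cannot test it. Such a stretch would hold the nearest genes. Within 1 Mb of Endov 2 of 30 genes changed (6.67%), against 8.31% of genes elsewhere without immunoglobulin genes. So few genes cannot show whether the excess reached the nearest genes. Carried-along DNA stays open. Clusters of related genes in this region could give the same excess, and the data hold no genotypes to decide.

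Of the genes measured, 34 of 55 interferon-stimulated and 9 of 11 MHC class II genes rose in knockout, beside some markers of other cell types, but neither list passed with an estimated correlation (adjusted p = 0.0602 and 0.0739). A lower share of macrophages would raise alike those markers of other types that macrophages do not make themselves. The medians of 7 marker lists spanned 0.96 on the log2 scale (permutation p = 0.000180, 100000 resamples), with erythroid markers lowest. The first version set the neutrophil list against the erythroid list alone (the same difference, permutation p = 0.00134). The lists hold genes that macrophages may make, such as Tfrc (erythroid list, 310 CPM in wild type) and Anxa1 (neutrophil list, 2257 CPM). For that reason, and because genes rather than libraries were shuffled, the test cannot decide whether the share of macrophages was lower. A rise of single cell types stays open too. The hypothesis of a response nearer to interferon-gamma than to type I interferon was tested on 9 GBP and IRG GTPases and 15 IFIT, OAS, MX and ISG genes, whose median log2 fold changes differed by 0.83 (exact permutation p = 0.000505). The first version set 25 genes leaning to interferon-gamma, MHC class II genes among them, against 26 leaning to type I, both lists drawn up after values had been seen, and gave 0.86 (permutation p = 2.00e-05, the smallest that 100000 resamples can give). Ifng itself had 8, 1 and 0 counts in wild type and 5, 6 and 8 in knockout, a ratio of 2.16 (exact 95% interval 0.931 to 5.42, counting error only), too few to show a difference. The GBP and IRG genes so rose more than the other families by their medians. These families were set against each other only after values had been seen. The genes are not independent, and GBP genes also respond to type I interferon. The difference therefore cannot decide whether the response was nearer to interferon-gamma.

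The libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. In each case 1 of the 10 splits, the real one, gave as many calls. It called 1119 genes against at most 1 in another split, 95 transcripts against 0, and 20 lists against 13. Every other split mixes wild-type and knockout libraries, so a difference between the groups of any cause would lower its calls. The splits therefore cannot tell an effect of genotype from another difference between the groups.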
